A study of Arthrobotrys flagrans with 9 samples.

How the data were processed

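RNA sequencing libraries came from hyphal cells of Arthrobotrys flagrans strain CIM1 after 0, 12 or 48 h with Caenorhabditis elegans extract, with 3 libraries per time. RNA was extracted with a plant RNA kit and libraries followed a standard Illumina protocol, per the labels' protocols. Reads were aligned with TopHat2 2.0.12 and Bowtie2 2.2.3, per the submitters' processing notes. No source used here stated how the authors counted reads, whether strand was used, how reads shared between genes were treated, or which genome build and annotation served. The deposited table held raw read counts per gene and library, per the file headers, and these values were whole numbers. It also held FPKM values per library and per time group that the authors computed, per the file headers, with a gene length that was not described. For each comparison the authors gave a log2 ratio of group means and a p-value with an adjusted p-value, per the file headers. Their test tool and normalization were not stated, and the group means beside these ratios were not used. Only the deposited counts entered the tests here. The authors' calls were compared with these tests, and their FPKM values were not used.

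The table listed 9991 genes on 29 contigs: 9397 predicted models, whose identifiers carry the prefix evm.model, and 594 whose identifiers start with another prefix for added genes. Gene names here are best hits to other organisms' proteins in the deposited annotation, so they name a similar protein and not a tested function. A best hit text was given for 5612 genes, and 4880 of these texts named a function. None of the identifiers matched the reference gene table (0 matches), so it was not used. Coordinates are those of the deposited table. Each per-library column was assigned to a sample from its name (0 columns without a sample), and 0 gene rows were blank.

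Total counts were 12978679, 12977059 and 11569906 for the libraries at 0 h, 10394853, 11742688 and 11801179 at 12 h, and 11164995, 11077644 and 12350889 at 48 h. A count of 0 in a library allows up to 3 counts, or 0.231 to 0.289 CPM before composition scaling. Intervals on ratios of summed counts are exact 95% binomial intervals and, like this floor, cover counting error only. Where the earlier group had 0 counts, the ratio was computed against a floor of 3 counts over the group, and where it had 1 to 3 counts the ratio is given with its interval. CPM values of genes were scaled with trimmed-mean (TMM) factors, which were 0.833 to 0.889 at 0 h, 1.029 to 1.048 at 12 h and 1.089 to 1.121 at 48 h.

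The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM factors and the filterByExpr filter by time group, which left 8760 genes and set aside 1231. All 9 libraries entered a single fit with time as the only factor and 6 residual degrees of freedom. The common biological coefficient of variation was 0.132. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 in each of the 3 comparisons. The SE of a log2 change was the change divided by the square root of its F statistic. Principal components were computed from log2 CPM with a prior count of 2. The chi-square between libraries used genes with at least 20 counts in the pair.

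The comparisons, tests, alternatives, 23 gene lists and rule for naming genes were fixed before the data were examined. The lists were text patterns searched in all annotation columns: subtilisin-like serine proteases, other secreted peptidases, chitin degradation, adhesins, lectins and surface proteins, cell wall synthesis, plant cell wall degradation, peroxisome, Woronin body and beta-oxidation, G protein and cAMP signalling, MAP kinase cascades, cytoplasmic ribosomal proteins, mitochondrial ribosomal proteins, ribosome biogenesis, respiratory chain and ATP synthase, antioxidant and NADPH oxidase, heat shock proteins and chaperones, proteasome, autophagy, nitrogen transport and use, sugar transporters, secondary metabolism, DNA replication, actin, septum and tubulin, and conidia and sporulation as markers of another cell state. A gene could be in several lists, and the term formin in the actin pattern also matched words such as forming, which made that list broad. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with adjustment over the 69 tests, and again with an estimated correlation. With an estimated correlation 0 of the 69 tests passed and 2 had an unadjusted p below 0.05. The smallest adjusted p of camera was then 0.471. A second list test, fry (limma), was run outside the fixed plan and adjusted over the same 69 tests. Its directional p-value was used, which asks whether the members shift to the same side between times. It does not ask whether they move more than other genes. The test allows for members that move together, and its direction was not kept. Genes were named if they were among the 10 largest log2 changes per direction and comparison. They needed an adjusted p below 0.05, a mean of at least 10 CPM over the 9 libraries, an informative annotation and non-overlapping libraries at the 2 times. The 2 list members with the smallest adjusted p at 12 h and at 48 h against 0 h were also named where they passed. The rule gave 98 genes, and genes 108 to 111 on contig 14 and those named in the closing part outside this rule were chosen after their values were seen.

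Alternatives were size factors by the median of ratios (RLE), library size only, the Wald test of DESeq2 1.42.0, no filter on low counts, a strict filter (10 CPM in 3 libraries), the 6 libraries of a comparison alone, the replicate number as a block, an absolute log2 change of at least 1, an adjusted p below 0.01, and each library left out in turn. For lists they were an estimated correlation and members found by the main description alone. Upper-quartile factors and library-size values for lists and named genes were added after the data were seen. The calls shared by 12 h and 48 h were set beside 20 simulated sets of unchanged groups against the same 0 h libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

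The gene test was checked on simulated counts with 200 changed genes. At a log2 change of 1, it recovered 82% of 100 genes for 12 h against 0 h (8700 genes fitted), 78% for 48 h against 0 h (8699 genes) and 80% for 48 h against 12 h (8701 genes). At a log2 change of 0.5 it recovered 26%, 23% and 26% of 100 genes, and it called 4, 5 and 3 unchanged genes. For 48 h against 0 h, a shift of 0.4 log2 seeded in the proteasome list was called, and 0 of the other lists were. Genes were drawn independently there, so the check does not show how camera behaves when members move together. The estimated correlation in the data reached 0.846, in the cytoplasmic ribosomal proteins.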

Results

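Arthrobotrys flagrans, also named Duddingtonia flagrans, is a nematode-trapping fungus that builds adhesive networks from its hyphae to catch nematodes. RNA was sequenced from hyphal cells of strain CIM1, grown on corn meal agar at 28 °C and treated with an extract of the nematode Caenorhabditis elegans. The treatment lasted 0, 12 or 48 h, and 3 libraries represented each time, so 9 libraries were compared. According to the series description, the question was how gene expression differs between periods of predation. The total count per library lay between 10394853 and 12978679. Of 9991 gene models, 8760 had enough counts to be tested. No untreated libraries at 12 h or 48 h are among the 9 samples, so time in culture and the extract were not separated. The labels did not say whether the 3 libraries of a time came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

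The 9 libraries grouped by time. The first principal component of log2 CPM (counts scaled by library total and TMM factor) held 65.3% of the variance and the second 21.4%. Libraries at 0 h had first-component scores from -58.30 to -53.74, and libraries at 12 h from 14.53 to 15.84. At 48 h, replicates 1 and 3 scored 49.92 and 43.79, while replicate 2 stood apart at 29.57, between them and the 12 h libraries. Across genes, which are not independent replicates, log2 CPM of 48 h replicate 2 correlated with 48 h replicates 1 and 3 at r = 0.979 and 0.980 and with the 12 h libraries at r = 0.972 to 0.977. By a chi-square per gene on the counts, where counting noise gives a value near 1, 48 h replicate 2 differed from 12 h replicates 1, 2 and 3 by 45.1, 59.9 and 24.4 and from 48 h replicates 1 and 3 by 45.2 and 46.6. The pair with the smallest chi-square, 12 h replicates 1 and 2, differed by 6.94, so no library was treated as a repeat of another.

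**Figure D1:**
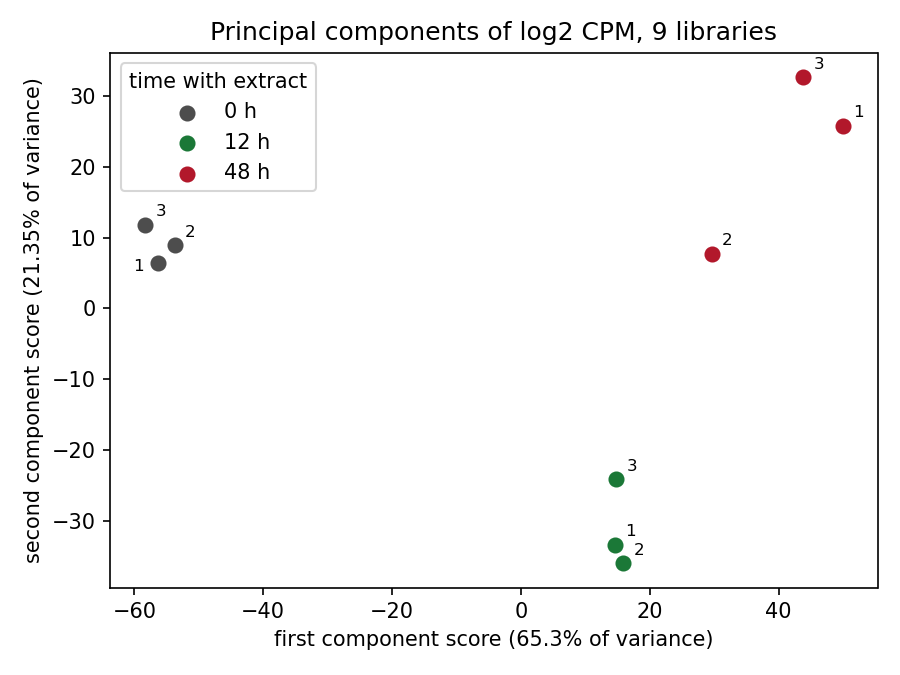
Scores of the 9 libraries on the first (65.3% of variance, x axis) and second (21.4%, y axis) principal components of log2 CPM; each point is 1 library, coloured by hours with extract and numbered by replicate. The 3 libraries at 0 h lie at -53.74 or below on the first component, and 48 h replicate 2 (29.57) lies between the 12 h libraries and the other 48 h libraries.

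After 12 h with extract, a subtilisin-like protease gene, a metalloprotease gene and an isp4-like transporter gene rose from low levels. Neither list of secreted proteases and peptidases passed the camera test, which sets a list against other genes. By fry, which tests the list's own members, adjusted p was 0.00662 for subtilisin-like serine proteases and 0.048 for other secreted peptidases. Of the other secreted peptidases, 5 were higher and 8 lower (median log2 change -0.22), so that value does not speak for a rise. Lists outside the proteases had smaller values, such as cell wall synthesis (fry adjusted p = 0.00059) and sugar transporters (fry adjusted p = 0.000698). The gene with a best hit to a cuticle-degrading serine protease (evm.model.Contig7.7, contig 7, 210720 to 212003, plus strand), a subtilisin-like enzyme of the kind that digests nematode cuticle, rose from 7.34 ± 3.22 CPM at 0 h to 216 ± 79.2 CPM at 12 h (SD, n = 3; log2 change 4.87, SE 0.52). Extracellular metalloprotease 1 (evm.model.Contig10.121, contig 10, 546203 to 547287, plus strand) rose from 4.78 ± 1.67 to 164 ± 37.3 CPM (log2 change 5.09, SE 0.46). An isp4-like gene (evm.model.Contig2.219), whose yeast relatives carry oligopeptides, rose from 4.02 ± 0.930 to 111 ± 23.3 CPM (log2 change 4.78, SE 0.44). The gene for a high-affinity glucose transporter, ght2 (evm.model.Contig14.138, contig 14, 515692 to 517522, minus strand), fell from 405 ± 65.4 to 15.3 ± 3.12 CPM (log2 change -4.72, SE 0.18). Alternative oxidase (evm.model.Contig1.1075, contig 1, 4022851 to 4024006, minus strand), which passes electrons from ubiquinol to oxygen without the later proton-pumping complexes, fell from 2585 ± 528 to 149.5 ± 8.32 CPM (log2 change -4.11, SE 0.29).

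Other named rises were a metallocarboxypeptidase A-like protein (evm.model.Contig3.987, log2 change 3.83, SE 0.40), the aspartic protease pep1 (evm.model.Contig2.1084, 3.30, SE 0.41) and a forkhead box protein L1 hit (evm.model.Contig1.83, 3.74, SE 0.34). Tyrosinase, a copper enzyme of melanin synthesis (evm.model.Contig4.856, 3.55, SE 0.95), rose too, as did 2 hits to WSC domain-containing protein 2 (evm.model.Contig2.819, 3.54, SE 0.73 and evm.model.Contig5.328, 4.26, SE 1.09). A hit to Repressed by EFG1 protein 1 (evm.model.Contig4.672) had 2 counts over the 0 h libraries and 116 over the 12 h libraries, a ratio of 53.4 (95% counting interval 14.5 to 446). Among falls, the largest was in a lipid phosphate phosphatase 3 hit (evm.model.Contig9.120, contig 9, 520041 to 521423, plus strand), from 1118 ± 185 to 2.01 ± 0.569 CPM (log2 change -9.13, SE 0.31). A glucose-repressible gene protein (evm.model.Contig1.854) fell from 4319 ± 1240 to 26.2 ± 17.4 CPM (log2 change -7.36, SE 0.71). Falls were also called in a probable phosphoketolase (evm.model.Contig7.335, log2 change -5.09), bli-3 (evm.model.Contig4.419, -4.82) and a hit to meiotically up-regulated gene 190 protein (evm.model.Contig11.206, -4.71). The same held for zinc finger protein rsv2 (evm.model.Contig8.387, -4.33), alcohol dehydrogenase 2 (evm.model.Contig4.908, -4.05) and Sec14 cytosolic factor, a phosphatidylinositol transfer protein (evm.model.Contig14.150, -3.96). Adjusted p from edgeR's quasi-likelihood test was 1.45e-05 to 0.0194 for the 10 rises and 7.16e-08 to 0.000111 for the 10 falls. Non-overlapping libraries at the 2 times were a condition for naming these genes and are no added support.

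Across the 8760 tested genes, 2247 were higher and 2329 lower at 12 h than at 0 h by edgeR's quasi-likelihood test (adjusted p below 0.05). Of the called genes, 462 rose and 838 fell by a log2 change of at least 1. The 3 libraries of one time did not overlap the 3 of the other in 62.4% of tested genes, where chance gives 10%. The direction of small changes depended on the scaling: with library size as the only scaling the split was 3996 higher and 1455 lower, 73.3% higher in place of 49.1%, and the median log2 change of all genes shifted by 0.27. The call of evm.model.Contig4.672 was lost without 0 h replicate 1, 0 h replicate 2, 0 h replicate 3 or 12 h replicate 2 (edgeR's quasi-likelihood test, adjusted p = 0.0526 to 0.0685), with a log2 change of 4.20 without 12 h replicate 2 in place of 5.51. Without that library the log2 changes of evm.model.Contig5.328, evm.model.Contig4.856 and evm.model.Contig2.819 were 3.52, 2.79 and 2.76. That of evm.model.Contig5.328 was 3.66 without 0 h replicate 1 and 5.31 without 0 h replicate 2. That of evm.model.Contig1.854 was -8.06 without 12 h replicate 3.

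Among the 23 gene lists fixed before the data were examined, the mitochondrial ribosomal proteins, which build the organelle's translation machinery, were higher at 12 h: 30 higher, 1 lower and 26 not called of 57 tested members, or 30 higher and 1 lower adjusted over the list alone (median log2 change 0.26, camera adjusted p = 0.00027, and adjusted p = 0.843 with an estimated correlation). Examples were 37S ribosomal protein S24 (evm.model.Contig5.496, log2 change 0.47, SE 0.08) and 54S ribosomal protein L4 (evm.model.Contig4.379, 0.55, SE 0.10). The list of peroxisome, Woronin body and beta-oxidation genes was lower: 6 higher, 26 lower and 18 not called of 50 tested members, or 6 higher and 26 lower adjusted over the list alone (median -0.33, camera adjusted p = 0.00878, and adjusted p = 0.781 with an estimated correlation). Its members included peroxisomal adenine nucleotide transporter 1 (evm.model.Contig1.1271, -2.78, SE 0.14) and the membrane protein PEX30 (evm.model.Contig9.255, -1.21, SE 0.10). With library size as the only scaling, the medians of these lists stayed on the same side, at 0.53 and -0.06. The other 21 lists did not pass the camera test at 12 h (adjusted p = 0.0715 to 0.865).

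Members of lists that did not pass still changed, but 52.2% of all tested genes were called at 12 h against 0 h. The counts below are to be read against that share. Subtilisin-like serine proteases gave 5 higher, 2 lower and 3 not called (5 and 2 adjusted over the list alone). Other secreted peptidases gave 5 higher, 8 lower and 5 not called (5 and 9 adjusted over the list alone). Chitin degradation gave 2 higher, 1 lower and 8 not called (1 and 1 adjusted over the list alone). Alkaline protease 2 (evm.model.Contig6.480), a subtilisin whose Aspergillus relative is vacuolar, fell (-0.52, SE 0.10, -0.25 with library size only, where the call was lost). Carboxypeptidase Y inhibitor (evm.model.Contig6.244), which is an inhibitor and not a peptidase, fell (-0.90, SE 0.11). Of the hits to beta-hexosaminidase, evm.model.Contig7.288 fell (-0.55, SE 0.07) and evm.model.Contig3.634 rose (0.42, SE 0.06). Cell wall synthesis gave 9 higher, 21 lower and 17 not called (9 and 25 adjusted over the list alone). Plant cell wall degradation gave 12 higher, 5 lower and 24 not called (9 and 4 adjusted over the list alone). Adhesins, lectins and surface proteins gave 2 higher, 1 lower and 7 not called (2 and 1 adjusted over the list alone). The wall enzymes 1,3-beta-glucanosyltransferase gas2 (evm.model.Contig1.1500, -1.70, SE 0.09) and chitin synthase G (evm.model.Contig2.112, -1.37, SE 0.09) fell. Pectinesterase (evm.model.Contig2.1104, -2.49, SE 0.20) fell, while endoglucanase type K (evm.model.Contig4.690, 2.27, SE 0.20) rose. The cargo receptor EMP46 (evm.model.Contig1.1337), in the lectin list for its lectin domain, fell (-0.41, SE 0.08, a call lost with library size only).

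Nitrogen transport and use gave 14 higher, 8 lower and 14 not called (14 and 8 adjusted over the list alone). Sugar transporters gave 0 higher, 6 lower and 8 not called (0 and 6 adjusted over the list alone). General amino-acid permease GAP1 (evm.model.Contig1.1130) rose from 9.73 ± 0.807 to 45.9 ± 7.21 CPM (log2 change 2.24, SE 0.20). NAD-specific glutamate dehydrogenase (evm.model.Contig1.1016), which breaks glutamate down, fell (-1.36, SE 0.10), and a high-affinity glucose transporter (evm.model.Contig2.972) fell (-0.91, SE 0.08). No sugar transporter was higher at an unadjusted p below 0.05 (0 of 14), and DESeq2 called 0. MAP kinase cascades gave 7 higher, 4 lower and 7 not called (8 and 4 adjusted over the list alone). G protein and cAMP signalling gave 16 higher, 19 lower and 28 not called (16 and 19 adjusted over the list alone). The osmotic-stress kinases PBS2 (evm.model.Contig9.175, contig 9, 720830 to 722807, plus strand) and hog1 (evm.model.Contig4.568, contig 4, 2067807 to 2073130, minus strand) fell together. PBS2 went from 541 ± 73.9 to 82.8 ± 1.02 CPM (log2 change -2.71, SE 0.10) and hog1 from 746 ± 96.6 to 170 ± 5.43 CPM (-2.13, SE 0.10). Septin-2 (evm.model.Contig4.319), a GTP-binding protein of the cytoskeleton listed with the G proteins, rose (1.39, SE 0.13). Antioxidant and NADPH oxidase gave 10 higher, 28 lower and 24 not called (10 and 29 adjusted over the list alone). Heat shock proteins and chaperones gave 8 higher, 17 lower and 18 not called (8 and 17 adjusted over the list alone). Proteasome gave 8 higher, 8 lower and 25 not called (8 and 7 adjusted over the list alone). Autophagy gave 15 higher, 19 lower and 27 not called (15 and 21 adjusted over the list alone). Glutaredoxin (evm.model.Contig5.203, -1.77, SE 0.11), a glutathione S-transferase omega-like protein (evm.model.Contig4.752, -2.47, SE 0.16) and glyoxalase 3 (evm.model.Contig4.459, -1.65, SE 0.11) fell.

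Cytoplasmic ribosomal proteins gave 1 higher, 1 lower and 65 not called (0 and 0 adjusted over the list alone). Ribosome biogenesis gave 13 higher, 25 lower and 59 not called (13 and 21 adjusted over the list alone). Respiratory chain and ATP synthase gave 7 higher, 12 lower and 43 not called (7 and 9 adjusted over the list alone). Secondary metabolism gave 6 higher, 12 lower and 11 not called (6 and 12 adjusted over the list alone). DNA replication gave 17 higher, 14 lower and 21 not called (17 and 14 adjusted over the list alone). Actin, septum and tubulin gave 107 higher, 61 lower and 113 not called (108 and 64 adjusted over the list alone). Conidia and sporulation, a marker list of another cell state, gave 6 higher, 4 lower and 5 not called (6 and 4 adjusted over the list alone). The replication licensing factor mcm3 (evm.model.Contig4.546, 0.83, SE 0.07) rose. Succinate dehydrogenase assembly factor 2 (evm.model.Contig5.587, -2.32, SE 0.11), probable polyketide synthase 1 (evm.model.Contig11.226, -1.49, SE 0.06) and a bifunctional P-450:NADPH-P450 reductase (evm.model.Contig3.988, -1.92, SE 0.21) fell. Lists were matched on annotation text, so some leading members have another main role. Examples are NAD-dependent malic enzyme in the chaperone list (evm.model.Contig1.123, -2.25, SE 0.22), and serine-threonine kinase receptor-associated protein (evm.model.Contig6.513, 0.89, SE 0.11) and a WD repeat protein (evm.model.Contig6.45, -0.52, SE 0.07) in the proteasome list. The autophagy list held uroporphyrinogen-III synthase, a heme enzyme (evm.model.Contig4.1004, -0.73, SE 0.07), and a glutamyl-tRNA amidotransferase subunit (evm.model.Contig12.70, 0.80, SE 0.09). Golgi pH regulator was in the replication list (evm.model.Contig1.1136, -0.86, SE 0.07). The ribosome biogenesis list held a regulator of phospholipase D, SRF1 (evm.model.Contig4.565, -1.60, SE 0.07), and protein-lysine methyltransferase efm3 (evm.model.Contig1.358, 1.41, SE 0.10). An NLRC3 hit was in the actin list (evm.model.Contig3.747, -1.81, SE 0.09), and sorting nexin-12 in the sporulation list (evm.model.Contig15.155, -0.65, SE 0.09). The cytoplasmic list's 2 calls were 60S ribosomal protein L10-A (evm.model.Contig6.399, -0.33, SE 0.10, -0.06 and not called with library size only) and the mitochondrial 54S protein L16 (evm.model.Contig6.643, 0.39, SE 0.13). Genes with no best hit were evm.model.Contig5.509 (-2.03, SE 0.14) in the G protein list, evm.model.Contig1.393 (-2.11, SE 0.10) in the actin list and evm.model.Contig2.490 (-1.81, SE 0.24) in the sporulation list. Each was called lower. The median and the mean log2 change differed in sign for other secreted peptidases (-0.22 and 0.15), chitin degradation (0.05 and -0.03), MAP kinase cascades (0.23 and -0.005) and proteasome (-0.03 and 0.03, where the camera direction was also up).

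The calls of L10-A and L16 were lost when 1 library was left out. L10-A lost it without 0 h replicate 2, 12 h replicate 2 or 12 h replicate 3 (edgeR's quasi-likelihood test, adjusted p = 0.0542 to 0.079), and L16 without 0 h replicate 1, 0 h replicate 2, 12 h replicate 1 or 12 h replicate 2 (edgeR's quasi-likelihood test, adjusted p = 0.0735 to 0.109). Library-size scaling turned the sign of the median in 12 of the 23 lists at 12 h, none of which had passed the test.

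**Figure D2:**
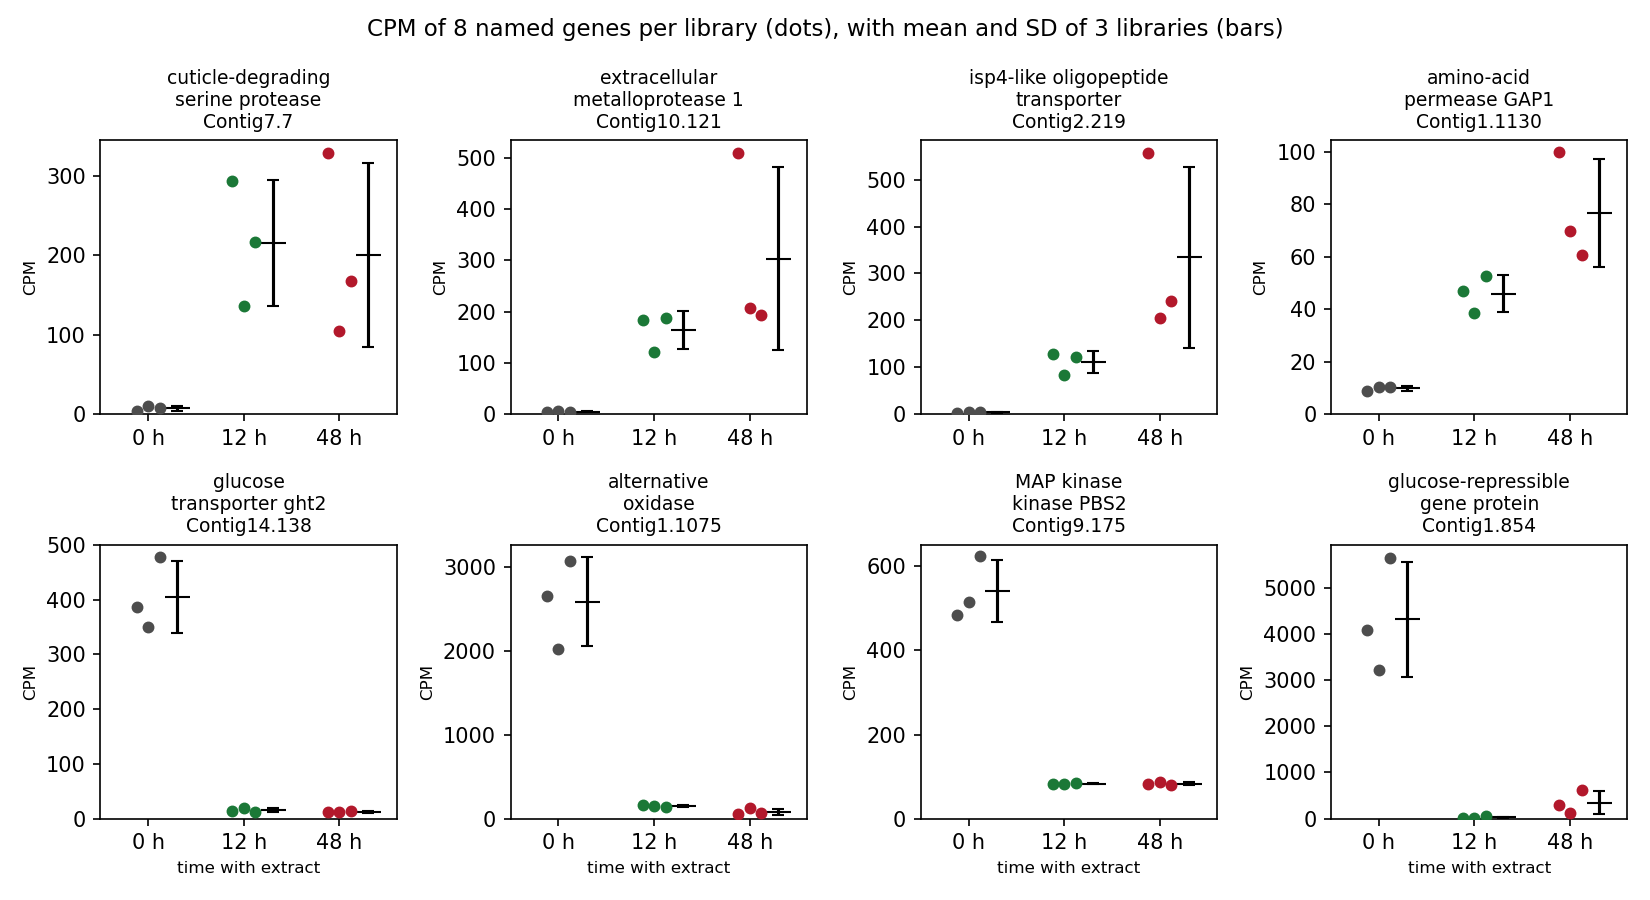
CPM (y axes, each from 0) of 8 named genes against hours with extract (x axes); dots are single libraries, and bars give the mean and SD of the 3 libraries of a time. The plotted proteases, the isp4-like transporter and GAP1 are higher at 12 h and 48 h than at 0 h under each scaling tried (GAP1 from 9.73 to 45.9 and 76.6 CPM), and ght2, alternative oxidase, PBS2 and the glucose-repressible gene are lower.

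At 48 h, the serine protease, metalloprotease and isp4-like genes that rose at 12 h were still above their 0 h levels. The cuticle-degrading serine protease (evm.model.Contig7.7) stood at 200.4 ± 116 CPM (SD, n = 3; log2 change from 0 h 4.77, SE 0.52). Extracellular metalloprotease 1 stood at 303 ± 179 CPM (5.98, SE 0.47) and the isp4-like gene at 334 ± 194 CPM (6.37, SE 0.46). Tyrosinase (evm.model.Contig4.856, contig 4, 3279437 to 3283082, plus strand) rose from 0.244 ± 0.0949 to 34.6 ± 13.3 CPM (log2 change 7.08, SE 0.75). A pair of neighbouring genes on contig 14 appeared at 48 h. A lovastatin diketide synthase LovF hit (evm.model.Contig14.106, contig 14, 383480 to 391980, minus strand), a polyketide synthase of secondary metabolism, reached 124 ± 73.4 CPM, and its neighbour, an acyl-CoA synthetase YngI hit (evm.model.Contig14.107, contig 14, 392760 to 395383, plus strand), reached 112 ± 78.4 CPM.

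The LovF hit had 3 counts over the 0 h libraries and 4904 at 48 h, a ratio of 1385 (95% counting interval 474 to 6720). The YngI hit had 0 and 4460 counts, at least 1260-fold higher against a floor of 3 counts over the group, with 95.8, 43.7 and 198 CPM in the 3 libraries at 48 h. Its fitted log2 change from 0 h was 13.38, or 12.66 without 48 h replicate 3 and 12.69 with DESeq2, and rested on 0 counts at 0 h. The Repressed by EFG1 protein 1 hit had 2 and 4272 counts, a ratio of 1810 (95% counting interval 501 to 14950). Further rises were called in the hits to WSC domain-containing protein 2 (evm.model.Contig5.328, log2 change 6.58, SE 0.97 and evm.model.Contig2.819, 6.44, SE 0.73) and a ribonuclease T2-like gene (evm.model.Contig12.240, 4.16, SE 0.42). Among falls, the lipid phosphate phosphatase 3 hit (-7.62, SE 0.28), ght2 (-5.02, SE 0.18) and alternative oxidase (-4.96, SE 0.30) were called lower at 48 h, as they were at 12 h. The same was true of rsv2 (-4.84, SE 0.32), Sec14 (-3.73, SE 0.22) and the glucose-repressible gene (-3.64, SE 0.59). Respiratory supercomplex factor 2 (evm.model.Contig13.35, contig 13, 136819 to 137598, plus strand) fell from 2435 ± 431 to 123 ± 22.2 CPM (-4.31, SE 0.18). Other falls were a cannabidiolic acid synthase-like 2 hit (evm.model.Contig1.991, -3.74, SE 0.33), the 30 kDa heat shock protein (evm.model.Contig7.50, -3.64, SE 0.70) and siderophore iron transporter mirC (evm.model.Contig1.1434, -3.39, SE 0.32). By edgeR's quasi-likelihood test, adjusted p was 3.12e-06 to 0.000264 for the 10 named rises and 9.75e-08 to 0.0014 for the 10 named falls.

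In all, 2600 genes were higher and 2686 lower at 48 h than at 0 h (edgeR's quasi-likelihood test, adjusted p below 0.05), and 914 and 861 of them changed by a log2 value of at least 1. Libraries of the 2 times did not overlap in 65.0% of tested genes, where chance gives 10%. As at 12 h, the split followed the scaling: with library size as the only scaling the split was 4660 higher and 1364 lower, 77.4% higher in place of 49.2%, and the median log2 change of all genes shifted by 0.36. Leaving out 48 h replicate 1 gave log2 changes of 5.79 for the isp4-like gene, 5.38 for metalloprotease 1 and 5.92 for evm.model.Contig5.328. The last had 5.98 without 0 h replicate 1 and 7.63 without 0 h replicate 2. The 30 kDa heat shock protein had -4.59 without 48 h replicate 2, and the glucose-repressible gene -4.32 without 48 h replicate 3.

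Of the gene lists, 4 passed the camera test at 48 h against 0 h, and in each the median was lower. Respiratory chain and ATP synthase genes gave 5 higher, 42 lower and 15 not called of 62 tested members, or 6 higher and 42 lower adjusted over the list alone (median log2 change -0.42, camera adjusted p = 0.000261, and adjusted p = 0.843 with an estimated correlation). They were led by succinate dehydrogenase assembly factors 2 (evm.model.Contig5.587, -2.42, SE 0.11) and 1A (evm.model.Contig7.59, -1.53, SE 0.15). Cytoplasmic ribosomal proteins gave 0 higher, 44 lower and 23 not called of 67 tested members, or 0 higher and 47 lower adjusted over the list alone (median -0.30, camera adjusted p = 0.000103, and adjusted p = 0.843 with an estimated correlation). Their median was 0.06 and the call was lost (camera adjusted p = 0.161) with library size as the only scaling. Peroxisome, Woronin body and beta-oxidation genes gave 6 higher, 27 lower and 17 not called of 50 tested members, or 6 higher and 28 lower adjusted over the list alone (median -0.38, camera adjusted p = 0.0054, and adjusted p = 0.781 with an estimated correlation). Cell wall synthesis genes gave 10 higher, 25 lower and 12 not called of 47 tested members, or 10 higher and 25 lower adjusted over the list alone (median -0.38, camera adjusted p = 0.0285, and adjusted p = 0.781 with an estimated correlation). In that list gas2 (-1.95, SE 0.10) and chitin synthase G (-1.34, SE 0.09) fell. With library size only, the medians of the respiratory, peroxisome and wall lists were -0.06, -0.03 and -0.02. None of the 67 cytoplasmic proteins was higher at an unadjusted p below 0.05, and DESeq2 called 0 higher. Among them, L10-A (-0.48, SE 0.10) and 40S protein S2 (evm.model.Contig3.527, -0.42, SE 0.10) fell, calls that were lost with library size only (-0.12 and -0.07).

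The other 19 lists did not pass at 48 h (camera adjusted p = 0.0715 to 0.998). Of all tested genes, 60.3% were called at 48 h against 0 h. Subtilisin-like serine proteases gave 5 higher, 2 lower and 3 not called (5 and 2 adjusted over the list alone). Other secreted peptidases gave 5 higher, 10 lower and 3 not called (5 and 10 adjusted over the list alone). The adjusted p of fry was 0.000934 for the subtilisin-like list and 0.00811 for the other peptidases. Lists outside the proteases had smaller values here too, such as cell wall synthesis (fry adjusted p = 0.000205). Chitin degradation gave 2 higher, 3 lower and 6 not called (2 and 2 adjusted over the list alone). A second alkaline protease 2 hit (evm.model.Contig9.12, 1.90, SE 0.37) and the metallocarboxypeptidase A-like protein (3.44, SE 0.40) rose. Beta-hexosaminidase 2 (evm.model.Contig1.1091, -0.63, SE 0.17, not called with library size only) fell. Beta-hexosaminidase evm.model.Contig7.288 had -0.32, SE 0.07 here and 0.04, not called, with library size only. Nitrogen transport and use gave 20 higher, 9 lower and 7 not called (21 and 10 adjusted over the list alone). Sugar transporters gave 4 higher, 7 lower and 3 not called (4 and 7 adjusted over the list alone). GAP1 rose to 76.6 ± 20.6 CPM (2.98, SE 0.20) and a purine permease (evm.model.Contig4.377, 1.59, SE 0.13) rose. A UDP-galactose transporter (evm.model.Contig2.683), which serves the Golgi and not sugar uptake, fell (-0.98, SE 0.10). Adhesins, lectins and surface proteins gave 3 higher, 4 lower and 3 not called (3 and 4 adjusted over the list alone). Plant cell wall degradation gave 17 higher, 6 lower and 18 not called (17 and 6 adjusted over the list alone), where an arabinofuranosidase (evm.model.Contig4.209, 1.34, SE 0.12) rose and pectinesterase (-2.56, SE 0.20) fell. MAP kinase cascades gave 9 higher, 4 lower and 5 not called (9 and 4 adjusted over the list alone), with PBS2 at 83.0 ± 2.93 CPM (-2.71, SE 0.10) and hog1 at 189.8 ± 4.15 CPM (-1.97, SE 0.10). G protein and cAMP signalling gave 25 higher, 19 lower and 19 not called (25 and 21 adjusted over the list alone).

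Antioxidant and NADPH oxidase gave 17 higher, 29 lower and 16 not called (17 and 31 adjusted over the list alone). Heat shock proteins and chaperones gave 7 higher, 22 lower and 14 not called (7 and 22 adjusted over the list alone). Proteasome gave 6 higher, 12 lower and 23 not called (6 and 10 adjusted over the list alone). Autophagy gave 19 higher, 18 lower and 24 not called (19 and 18 adjusted over the list alone). Glutaredoxin (-2.05, SE 0.11), glyoxalase 3 (-1.47, SE 0.11) and DnaJ homolog subfamily C member 3, a chaperone of the endoplasmic reticulum (evm.model.Contig12.45, -0.86, SE 0.07), fell. The unfolded-protein-response regulator hacA (evm.model.Contig11.55), listed with autophagy, rose (2.10, SE 0.19). So did a HET-E-1 hit listed with the proteasome (evm.model.Contig1.913, 1.20, SE 0.12), whereas translation initiation factor 2A in that list fell (evm.model.Contig2.845, -0.72, SE 0.08). Mitochondrial ribosomal proteins gave 2 higher, 8 lower and 47 not called (1 and 6 adjusted over the list alone). Ribosome biogenesis gave 14 higher, 44 lower and 39 not called (14 and 44 adjusted over the list alone). DNA replication gave 17 higher, 15 lower and 20 not called (17 and 15 adjusted over the list alone). Actin, septum and tubulin gave 95 higher, 80 lower and 106 not called (95 and 80 adjusted over the list alone). Within them, 37S protein rsm18 (evm.model.Contig6.386, -0.49, SE 0.08, not called with library size only) fell and 54S protein L11 (evm.model.Contig5.93, 0.61, SE 0.12) and mcm3 (0.74, SE 0.07) rose. Secondary metabolism gave 7 higher, 11 lower and 11 not called (7 and 11 adjusted over the list alone). Conidia and sporulation, the markers of another cell state, gave 5 higher, 5 lower and 5 not called (5 and 5 adjusted over the list alone). The spore regulator wetA (evm.model.Contig5.609) rose from 18.4 ± 2.27 to 55.0 ± 9.80 CPM (1.58, SE 0.18). Listed genes without a best hit that rose were evm.model.Contig5.235 (3.30, SE 0.25) in the antioxidant list and evm.model.Contig3.29 (3.61, SE 0.28) in the secondary metabolism list. Other leading members outside their list's theme were actin-related protein 8, a chromatin factor (evm.model.Contig9.365, 0.56, SE 0.06), in the peptidase list and an uncharacterized protein (evm.model.Contig4.366, -1.57, SE 0.12) in the peroxisome list. Median and mean differed in sign for 7 lists, among them other secreted peptidases (-0.34 and 0.13), chitin degradation (0.05 and -0.07) and adhesins (-0.16 and 1.60). The others were autophagy (-0.05 and 0.12), sugar transporters (-0.14 and 0.003), secondary metabolism (-0.05 and 0.06) and actin (0.02 and -0.01). The camera direction was up for adhesins and autophagy. Library-size scaling turned the sign of the median in 10 of the 23 lists, of which the cytoplasmic ribosomal proteins had passed.

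Between 12 h and 48 h, the contig 14 gene pair, tyrosinase and a phosphate transporter rose, and the genes mirC, FET3 and NADP-specific glutamate dehydrogenase fell. The LovF hit went from 9 to 4904 counts, a 501-fold difference (95% counting interval 264 to 1097). The YngI hit went from 3 to 4460 counts, a ratio of 1368 (95% counting interval 468 to 6637). Tyrosinase rose from 2.99 ± 2.41 to 34.6 ± 13.3 CPM (SD, n = 3; log2 change 3.53, SE 0.52). An inorganic phosphate transporter C8E4.01c hit (evm.model.Contig5.400, contig 5, 1357206 to 1359854, minus strand) rose from 47.8 ± 37.9 to 357 ± 119 CPM (2.90, SE 0.56). Siderophore iron transporter mirC (evm.model.Contig1.1434, contig 1, 5337409 to 5339471, minus strand) fell from 48.1 ± 11.7 to 15.5 ± 7.39 CPM (-1.64, SE 0.31). The iron multicopper oxidase FET3 (evm.model.Contig9.103, contig 9, 458900 to 460871, plus strand) fell from 30.8 ± 9.03 to 10.1 ± 0.533 CPM (-1.62, SE 0.21). NADP-specific glutamate dehydrogenase (evm.model.Contig4.1030), which fixes ammonium into glutamate, fell from 2947 ± 478 to 955 ± 714 CPM (-1.63, SE 0.42), a call lost without 12 h replicate 1, 12 h replicate 2, 48 h replicate 1 or 48 h replicate 3, and with the 6 libraries of the comparison alone.

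Other named rises from 12 h to 48 h were the Repressed by EFG1 protein 1 hit (log2 change 5.07, SE 0.62), the glucose-repressible gene (3.73, SE 0.60) and the probable phosphoketolase (3.13, SE 0.51). The last 2 were below their 0 h levels at 48 h (log2 changes -3.64 and -1.96). Rises were also called in a heat shock 70 kDa protein 12B hit (evm.model.Contig7.354, 3.39, SE 0.66), an NFX1-type zinc finger hit (evm.model.Contig5.690, 2.93, SE 0.51) and WSC domain-containing protein 2 (evm.model.Contig2.819, 2.90, SE 0.56). Named falls also included SnodProt1, a small secreted cerato-platanin-like protein (evm.model.Contig12.67, -1.90, SE 0.55), alcS (evm.model.Contig10.98, -1.70, SE 0.39) and O-acetylhomoserine (thiol)-lyase, a methionine synthesis enzyme (evm.model.Contig2.991, -1.68, SE 0.36). They included, too, glucan 1,3-beta-glucosidase (evm.model.Contig2.1459, -1.64, SE 0.39), vitamin H transporter 1, a biotin carrier (evm.model.Contig5.629, -1.53, SE 0.27), the mitochondrial carrier Aralar1 (evm.model.Contig8.49, -1.53, SE 0.49) and a mutanase (evm.model.Contig14.60, -1.51, SE 0.35). The adjusted p from edgeR's quasi-likelihood test was 0.000152 to 0.00823 for the 10 rises and 0.00282 to 0.0471 for the 10 falls.

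**Figure D3:**
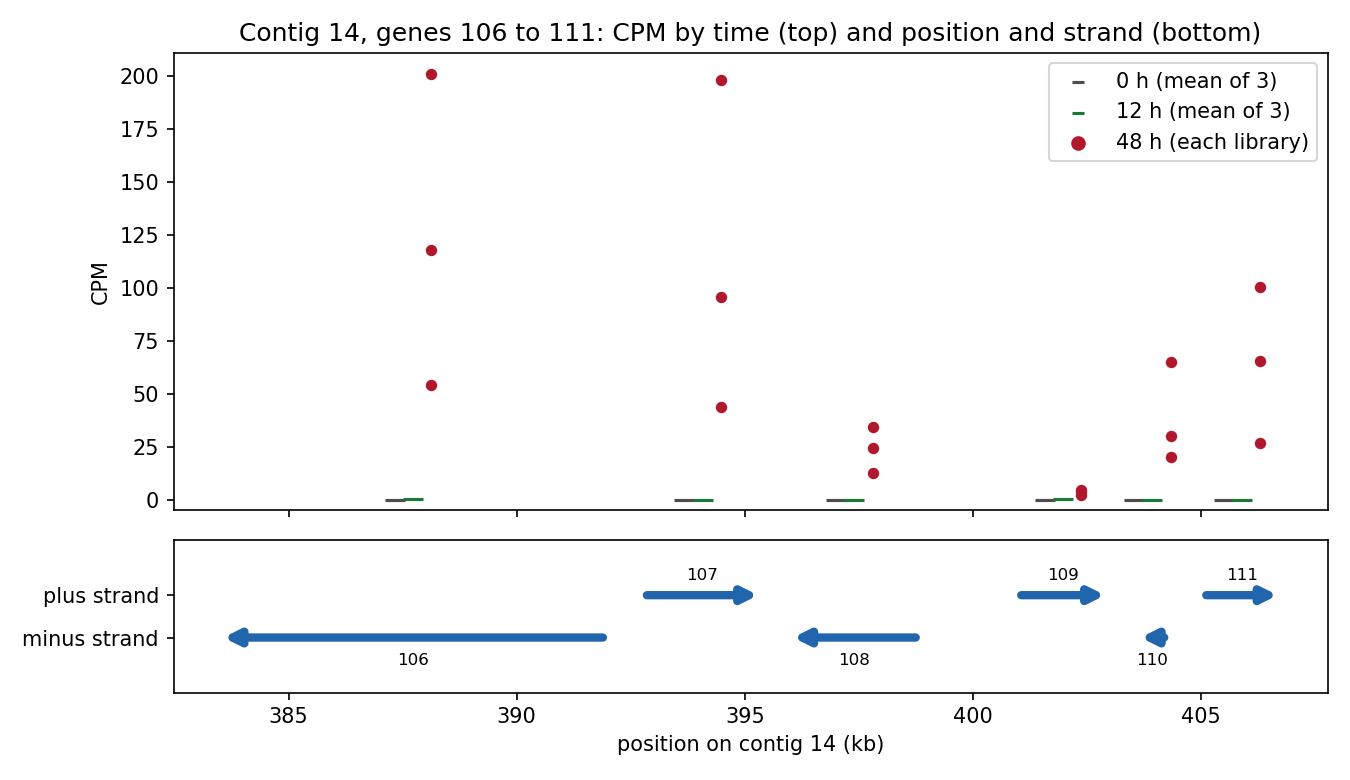
Top, CPM (y axis) of genes 106 to 111 on contig 14, with each 48 h library as a dot and the 0 h and 12 h means of 3 libraries as dashes; bottom, position (x axis, kb) and strand of each gene as an arrow. All 6 genes lie near 0 at 0 h and 12 h, and at 48 h their means run from 3.52 CPM (gene 109) to 124 CPM (gene 106), with 48 h replicate 2 the lowest of its time for each.

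By edgeR's quasi-likelihood test, 1105 genes were higher and 947 lower at 48 h than at 12 h (adjusted p below 0.05), with 409 and 133 at a log2 change of at least 1. The 2 times did not overlap in 42.2% of tested genes, where chance gives 10%. These counts varied with the library left out. They were 457 and 327 without 12 h replicate 1 and 458 and 324 without 12 h replicate 2. Without 12 h replicate 3 they were 1039 and 884. They were 729 and 522 without 48 h replicate 1, 494 and 322 without 48 h replicate 3, and 1371 and 1343 without 48 h replicate 2, the library that stood apart. For scaling, with library size as the only scaling the split was 1577 higher and 582 lower, 73.0% higher in place of 53.9%, and the median log2 change of all genes shifted by 0.09.

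Of the 10 named falls, 6 lost their call when 1 library was left out. SnodProt1 lost it without 12 h replicate 1, 12 h replicate 2, 48 h replicate 1 or 48 h replicate 3 (edgeR's quasi-likelihood test, adjusted p = 0.0799 to 0.111). The alcS gene lost it without 12 h replicate 2 or 48 h replicate 3 (edgeR's quasi-likelihood test, adjusted p = 0.0531 to 0.0599). The glucosidase lost it without 12 h replicate 1, 12 h replicate 2 or 48 h replicate 3 (edgeR's quasi-likelihood test, adjusted p = 0.0607 to 0.068). Glutamate dehydrogenase lost it without 12 h replicate 1, 12 h replicate 2, 48 h replicate 1 or 48 h replicate 3 (edgeR's quasi-likelihood test, adjusted p = 0.06 to 0.0746). Aralar1 lost it without 0 h replicate 1, 0 h replicate 2, 0 h replicate 3, 12 h replicate 1, 12 h replicate 2, 48 h replicate 1 or 48 h replicate 3 (edgeR's quasi-likelihood test, adjusted p = 0.0557 to 0.137). The mutanase lost it without 12 h replicate 1, 12 h replicate 2 or 48 h replicate 3 (edgeR's quasi-likelihood test, adjusted p = 0.0501 to 0.0592). With the 6 libraries compared alone, the calls of SnodProt1, glutamate dehydrogenase and Aralar1 were lost as well (edgeR's quasi-likelihood test, adjusted p = 0.0679, 0.0518 and 0.0809), with log2 changes of -1.90, -1.63 and -1.53. Without 48 h replicate 2, the log2 changes of these 6 genes were -2.93, -2.47, -2.31, -2.44, -2.39 and -2.20. Among rises, without 12 h replicate 2 the log2 change was 6.40 for evm.model.Contig4.672, 4.30 for tyrosinase and 3.70 for evm.model.Contig2.819. For evm.model.Contig14.107 it was 13.38 without that library and 9.51 without 48 h replicate 3. Without 12 h replicate 3 it was 4.42 for the glucose-repressible gene, 4.18 for heat shock protein 12B, 3.64 for the NFX1-type gene and 3.78 for the phosphate transporter. Without 48 h replicate 3 it was 3.04 for the glucose-repressible gene and 2.74 for heat shock protein 12B.

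From 12 h to 48 h, 5 gene lists passed, each with a lower median. Mitochondrial ribosomal proteins gave 0 higher, 32 lower and 25 not called of 57 tested members, or 0 higher and 41 lower adjusted over the list alone (median log2 change -0.35, camera adjusted p = 4.1e-13, and adjusted p = 0.781 with an estimated correlation). The S24 protein that had risen at 12 h fell (-0.40, SE 0.08). Respiratory chain and ATP synthase genes gave 0 higher, 26 lower and 36 not called of 62 tested members, or 1 higher and 36 lower adjusted over the list alone (median -0.31, camera adjusted p = 4.97e-09, and adjusted p = 0.781 with an estimated correlation). Cytoplasmic ribosomal proteins gave 0 higher, 12 lower and 55 not called of 67 tested members, or 0 higher and 0 lower adjusted over the list alone (median -0.27, camera adjusted p = 1.88e-10, and adjusted p = 0.843 with an estimated correlation). With library size only, these medians were -0.26, -0.21 and -0.18. Cell wall synthesis gave 1 higher, 11 lower and 35 not called of 47 tested members, or 2 higher and 12 lower adjusted over the list alone (median -0.10, camera adjusted p = 0.0299, and adjusted p = 0.781 with an estimated correlation). That call was lost with library size only (camera adjusted p = 0.0567), without 12 h replicate 3 (0.0746) and without 48 h replicate 1 (0.061). The actin, septum and tubulin list gave 17 higher, 53 lower and 211 not called of 281 tested members, or 19 higher and 58 lower adjusted over the list alone (median -0.07, or 0.02 with library size only, camera adjusted p = 0.0285, and adjusted p = 0.471 with an estimated correlation). Its text pattern also matched words such as forming. The call was lost with members taken from the main description alone (camera adjusted p = 0.132), with library size only (0.0896) and without 48 h replicate 2 (0.086).

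The other 18 lists did not pass from 12 h to 48 h (camera adjusted p = 0.056 to 0.933). Of all tested genes, 23.4% were called at 48 h against 12 h. Nitrogen transport and use gave 10 higher, 3 lower and 23 not called (11 and 3 adjusted over the list alone). Sugar transporters gave 4 higher, 1 lower and 9 not called (4 and 1 adjusted over the list alone). In them, the purine permease was higher at 48 h than at 12 h (0.69, SE 0.13), and so was GAP1 (0.74, SE 0.18), with a call lost without 12 h replicate 1 or 2 (edgeR's quasi-likelihood test, adjusted p = 0.0633 and 0.0787). Subtilisin-like serine proteases gave 0 higher, 0 lower and 10 not called (0 and 0 adjusted over the list alone), where 2 of the 10 members were higher at an unadjusted p below 0.05 and DESeq2 called 1. Other secreted peptidases gave 0 higher, 2 lower and 16 not called (0 and 2 adjusted over the list alone), with 1 higher at an unadjusted p below 0.05 and 1 with DESeq2. Chitin degradation gave 1 higher, 1 lower and 9 not called (1 and 2 adjusted over the list alone). Adhesins, lectins and surface proteins gave 3 higher, 2 lower and 5 not called (3 and 3 adjusted over the list alone). Plant cell wall degradation gave 5 higher, 2 lower and 34 not called (5 and 2 adjusted over the list alone). Peroxisome, Woronin body and beta-oxidation gave 5 higher, 4 lower and 41 not called (5 and 3 adjusted over the list alone). Antioxidant and NADPH oxidase gave 14 higher, 4 lower and 44 not called (14 and 4 adjusted over the list alone). Secondary metabolism gave 5 higher, 3 lower and 21 not called (5 and 3 adjusted over the list alone). Heat shock proteins and chaperones gave 7 higher, 9 lower and 27 not called (7 and 11 adjusted over the list alone). Proteasome gave 1 higher, 2 lower and 38 not called (0 and 1 adjusted over the list alone). Autophagy gave 7 higher, 6 lower and 48 not called (7 and 6 adjusted over the list alone). Ribosome biogenesis gave 1 higher, 11 lower and 85 not called (0 and 3 adjusted over the list alone). DNA replication gave 3 higher, 3 lower and 46 not called (3 and 3 adjusted over the list alone). G protein and cAMP signalling gave 6 higher, 7 lower and 50 not called (6 and 5 adjusted over the list alone). MAP kinase cascades gave 3 higher, 3 lower and 12 not called (4 and 3 adjusted over the list alone). Conidia and sporulation gave 3 higher, 1 lower and 11 not called (4 and 1 adjusted over the list alone). The sporulation regulator wetA was higher at 48 h (0.77, SE 0.17), a call lost without 12 h replicate 1, 12 h replicate 2 or 48 h replicate 3 (edgeR's quasi-likelihood test, adjusted p = 0.0527 to 0.0553). Median and mean differed in sign for adhesins (-0.04 and 0.83), peroxisome (-0.04 and 0.05) and DNA replication (-0.007 and 0.02). Library-size scaling turned the median's sign in 8 of the 23 lists, of which the actin list had passed. In the 3 ribosomal and respiratory lists, 0 members were called higher, with 1 respiratory member at an unadjusted p below 0.05 and 0 calls by DESeq2.

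Most genes that differed from 0 h at one time differed in the same direction at the other. Of the genes called against 0 h, 1733 were higher and 1919 lower at both times, 3652 in all, while 17 were higher at 12 h and lower at 48 h and 18 the reverse. Independent lists of these sizes would share 1381 genes in the same direction. Both comparisons use the same 0 h libraries: in 20 simulated sets of unchanged groups set against those libraries, edgeR's quasi-likelihood test called 0 genes in the same direction, or 96.8 on average at an unadjusted p below 0.05. Across genes, the covariance of the log2 changes was 0.873 (r = 0.807) against a simulated 0.0224 (r = 0.515), a difference of 0.850. The simulated values already include the sharing of the 0 h libraries, which alone did not give a covariance near the observed one. How sharing acts on the counts when genes do change was not simulated. A further 889 genes were called at 12 h alone and 1599 at 48 h alone, of which 391 and 739 also passed the test of 48 h against 12 h, so most of these genes were not shown to differ between the 2 times.

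The authors' deposited table marked 1752 genes up and 2072 down at 12 h against 0 h, 1895 and 2054 at 48 h against 0 h, and 673 and 628 at 48 h against 12 h, with a test whose tool was not stated. Of the marked genes that were tested here, 3699 of 3814, 3890 of 3907 and 1229 of 1289 were called here in the same direction by edgeR's quasi-likelihood test. None (0) were called in the opposite direction in each comparison. Both sets of calls came from the same 9 libraries, so this overlap is not independent support. Reads from near-identical paralogs and from overlapping or antisense genes could not be told apart, because the authors' handling of strand and shared reads was not stated.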

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

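The tests of a mixture, a swap, depth, gene length, scaling and run-on reads, and the run that left each library out for the genes below, were chosen after the results were seen. The effects of 12 h and of 48 h against 0 h differed in 5 gene lists and in 50 of the 98 named genes by the test of 48 h against 12 h (camera for lists, edgeR's quasi-likelihood test for genes), and these 55 results are given here as log2 differences, 48 h minus 12 h. Of the 50 genes, 20 were named from this same comparison, where a call was required, so the share of 50 in 98 says nothing about genes at large, of which 23.4% were called. With an estimated correlation none of the 5 lists passed (camera adjusted p = 0.471 to 0.843), so their camera calls depend on the preset correlation. The rule for single outlying libraries covers groups of 4 to 10, so 0 groups had that test. The list medians were -0.35 for mitochondrial ribosomal proteins, -0.31 for the respiratory chain and ATP synthase, -0.27 for cytoplasmic ribosomal proteins, -0.10 for cell wall synthesis and -0.068 for actin, septum and tubulin (the last at 0.02 with library size only).

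Of the 50 genes, 31 were higher and 19 lower at 48 h, and 20 were called whichever library was left out, while 30 lost their call without at least 1 library (edgeR's quasi-likelihood test, adjusted p up to 0.167). Called in every such run and higher at 48 h were the YngI hit (10.20), the LovF hit (8.87), the Repressed by EFG1 protein 1 hit (5.07), the glucose-repressible gene (3.73), tyrosinase (3.53), heat shock 70 kDa protein 12B (3.39), phosphoketolase (3.13) and the NFX1-type gene (2.93). So were the WSC gene evm.model.Contig2.819 (2.90), phosphate transporter C8E4.01c (2.90), ribonuclease T2-like (1.81), lipid phosphate phosphatase 3 (1.51), evm.model.Contig3.29 (1.18), the purine permease (0.69) and polyketide synthase 1 (0.37). Called in every such run and lower at 48 h were O-acetylhomoserine (thiol)-lyase (-1.68), mirC (-1.64), FET3 (-1.62), vitamin H transporter 1 (-1.53) and 37S protein S24 (-0.40). Higher at 48 h, with a call lost in at least 1 run, were bli-3 (2.51), the WSC gene evm.model.Contig5.328 (2.32), meiotically up-regulated gene 190 (1.69), the isp4-like gene (1.59), alcohol dehydrogenase 2 (1.15), NAD-dependent malic enzyme (0.96), evm.model.Contig5.235 (0.83) and wetA (0.77). This group also held GAP1 (0.74), hacA (0.64), glutathione S-transferase omega-like 2 (0.53), peroxisomal adenine nucleotide transporter 1 (0.48), the HET-E-1 hit (0.38), the arabinofuranosidase (0.38), high-affinity glucose transporter (0.31) and beta-hexosaminidase evm.model.Contig7.288 (0.23). Lower at 48 h, with a call lost in at least 1 run, were SnodProt1 (-1.90), alcS (-1.70), glucan 1,3-beta-glucosidase (-1.64), NADP-specific glutamate dehydrogenase (-1.63), Aralar1 (-1.53), the mutanase (-1.51) and cannabidiolic acid synthase-like 2 (-1.11). Also lower were alternative oxidase (-0.85), respiratory supercomplex factor 2 (-0.66), endoglucanase type K (-0.59), 54S protein L4 (-0.37), 40S protein S2 (-0.33), DnaJ homolog C3 (-0.26) and beta-hexosaminidase evm.model.Contig3.634 (-0.21). Calls lost numbered 26 without 12 h replicate 1, 29 without 12 h replicate 2, 7 without 12 h replicate 3, 20 without 48 h replicate 1, 3 without 48 h replicate 2 and 27 without 48 h replicate 3, and 5, 4 and 2 without 0 h replicates 1, 2 and 3. Without 48 h replicate 1 the log2 difference was 1.01 for the isp4-like gene and 1.66 for evm.model.Contig5.328, and the latter was 3.07 without 12 h replicate 2. The fitted changes of the LovF and YngI hits rest on near-zero counts at earlier times and are no bounds. The Repressed by EFG1 protein 1 hit had 116 counts over the 12 h libraries and 2 over the 0 h libraries, so near-zero counts affect its changes from 0 h. Its difference between 48 h and 12 h was 6.40 without 12 h replicate 2.

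The 6 libraries of a comparison can be parted into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 4576 genes for 12 h against 0 h, 5286 for 48 h against 0 h and 2052 for 48 h against 12 h, and 1 split of 10, the real one, reached this count in each. The highest of the other splits called 0 genes by edgeR's quasi-likelihood test in each comparison, or 240, 341 and 1485 genes at an unadjusted p below 0.05, against 5052, 5636 and 3358 for the real splits. Any other split puts the difference between times inside its groups and widens their spread, so its 0 calls say little about chance. The 1485 came from the split that joined 48 h replicate 2 with 12 h replicates 1 and 2.

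In the first pattern, 48 h replicate 2 lay between the 12 h libraries and the other 48 h libraries (first-component score 29.57, against 14.53 to 15.84 and 43.79 to 49.92). A swap with a 12 h library is argued against, because the 12 h libraries lay 27.95 below the lower of the other 48 h libraries and spanned only 1.31 among themselves. Low depth is argued against by its total of 11077644 counts, within the 10394853 to 12978679 of the others. A sample mixed with 12 h RNA in 1 proportion stays open: the median share of 12 h RNA was 0.595 in rising and 0.472 in falling genes, a difference of 0.123 (bootstrap 95% interval 0.087 to 0.162), and the -0.003 to 0.110 of computed mixtures overlaps this interval. The bootstrap resampled genes, so its interval does not measure a spread between libraries. A slower response of that culture may also account for the pattern and was not tested.

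In the second pattern, the ribosomal and respiratory lists fell together from 12 h to 48 h, with a combined median of -0.30 over 185 genes. Gene length as the whole cause is argued against, since the median was -0.42 (bootstrap 95% interval -0.43 to -0.39) after a length trend was removed. A trend with expression level, planned before its result was seen, left -0.22 (bootstrap 95% interval -0.26 to -0.20), and library size as the only scaling left -0.21 (bootstrap 95% interval -0.23 to -0.18). Removing the expression trend left list medians of -0.37 for mitochondrial ribosomal proteins, -0.26 for the respiratory list and -0.14 for cytoplasmic ribosomal proteins. Without that correction they were -0.35, -0.31 and -0.27. These bootstraps resampled the 185 genes and not libraries, so the intervals do not measure the spread between libraries. With the correlation between members estimated, the adjusted p of camera was 0.781 to 0.843, so a fall beyond that of other genes depends on the preset correlation. The adjusted p of fry was 0.0327 for mitochondrial ribosomal proteins, 0.0379 for the respiratory list and 0.0681 for cytoplasmic ribosomal proteins. For the first 2 lists this argues against members that move together without a difference between times, and for the third that stays open. A change in growth between 12 h and 48 h is a candidate explanation that the design cannot part from time in culture.

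In the third pattern, 6 neighbouring genes on contig 14 (evm.model.Contig14.106 to evm.model.Contig14.111, positions 383480 to 406767) together had 9 counts at 0 h, 23 at 12 h and 14482 at 48 h, with 4236, 1922 and 8324 counts in 48 h replicates 1, 2 and 3. The genes with names are the LovF polyketide synthase hit, the YngI acyl-CoA synthetase hit and a pyruvate decarboxylase hit (evm.model.Contig14.108, 934 counts over the 48 h libraries), and genes 109, 110 and 111 without names had 136, 1523 and 2525 counts. Reads running on from 1 gene into its neighbours stay open, although the genes of 3 of the 5 neighbouring pairs point away from each other. The handling of strand was not stated, so such reads may have been counted in genes of either strand. Chance placement is argued against, since 0 of 1000 shuffles of gene order gave a run of 6 among the 71 genes rising by over 3 log2 (longest run 3), a test planned before its result was seen. The genes may form a co-regulated cluster of secondary metabolism, a hypothesis found and tested on the same data, and shared reads with genes elsewhere could not be examined.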

How the results depend on the processing

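Upper-quartile factors, and library size alone for lists and named genes, were chosen after the data were seen, and the other alternatives were fixed before. Size factors by the median of ratios, DESeq2's Wald test, no filter, the strict filter and the 6 libraries alone kept each count of genes within 1.5 times of its main value (for example 2007 to 2354 genes higher at 12 h). Library size only gave 3996 higher and 1455 lower at 12 h against 0 h, 4660 and 1364 at 48 h against 0 h, and 582 lower at 48 h against 12 h. Composition factors, which it leaves out, were lower at 0 h (0.833 to 0.889) than later. Upper-quartile factors gave 1781 lower at 48 h against 0 h. A log2 change of at least 1 left 462 and 838, 914 and 861, and 409 and 133 genes, with 1007 shared in direction, and an adjusted p below 0.01 left 348 and 224 genes for 48 h against 12 h, as stricter thresholds do. Leaving out 1 library gave 1873 to 2367 higher and 1963 to 2443 lower at 12 h, 2317 to 2603 and 2370 to 2802 at 48 h, 457 to 1371 and 322 to 1343 for 48 h against 12 h, 3228 to 3672 shared and 10 to 15 lists. For 48 h against 12 h the counts were 457 and 327 without 12 h replicate 1, 458 and 324 without 12 h replicate 2, 729 and 522 without 48 h replicate 1, 494 and 322 without 48 h replicate 3, and 1371 and 1343 without 48 h replicate 2. The cause was not tested. With an estimated correlation 0 of the 69 list tests passed, in place of 11 (2 at an unadjusted p below 0.05, camera), 12 passed with members from the main description and 8 with library size only. Of the 145 named-gene results, beta-hexosaminidase evm.model.Contig7.288 changed sign with library size only (0.04 at 48 h against 0 h), 7 others lost their call there, and 34 calls were lost over the runs without 1 library. The 6 libraries alone ended 3 calls, those of SnodProt1, NADP-specific glutamate dehydrogenase and Aralar1 for 48 h against 12 h, and the cause was not tested. Pseudocounts, filters on normalized values and quantile normalization were not run, because counts were deposited. Depth limits genes near 0, where a library's floor was 0.231 to 0.289 CPM.

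With the replicate number as a block, calls were 2152 and 2275 at 12 h, 2531 and 2655 at 48 h, 1062 and 840 for 48 h against 12 h, 3543 shared and 11 lists, and no call changed in the 69 list tests or the 145 named-gene results. Those results cover a gene only in the comparisons it was named for, so the calls of other named genes for 48 h against 12 h were not run with the block. Libraries sharing a number deviated together at r = -0.109 to 0.223 across genes, over 0.1 in 2 of 9 pairs, and 3 of 9 libraries correlated best with their own number, so the pairing is by number only.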

Other observations

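All lists in this part were chosen after the results were seen, though the tests of phosphate and amino acid genes left out the members first noticed. Aminoacyl-tRNA synthetases, which load amino acids onto tRNA, rose at 12 h: 26 of 34 members were called higher and 1 lower against 0 h (median log2 change 0.48, camera adjusted p = 3.6e-07, and adjusted p = 0.581 with an estimated correlation). At 48 h, 21 were higher and 2 lower than at 0 h (0.29, camera adjusted p = 0.00482, and 0.66 with an estimated correlation). From 12 h to 48 h, 11 fell and 0 rose (-0.19, camera adjusted p = 4.62e-05, and 0.581 with an estimated correlation), with 2 higher at an unadjusted p below 0.05 and 1 by DESeq2. Each of these medians had the same sign under every scaling tried (0.74, 0.64 and -0.10 with library size only).

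Of the 35 genes called in opposite directions at 12 h and 48 h against 0 h, 6 are given here as examples chosen by annotation, and whether any role is over-represented among the 35 was not tested. 2-isopropylmalate synthase of leucine synthesis (evm.model.Contig9.108) had 112 ± 9.56, 135 ± 4.69 and 80.7 ± 10.4 CPM at 0, 12 and 48 h (SD, n = 3). Aspartate-semialdehyde dehydrogenase (evm.model.Contig4.340) had 123 ± 3.36, 163 ± 12.1 and 101 ± 16.5 CPM, and the histidine biosynthesis trifunctional protein (evm.model.Contig1.268) 196 ± 15.3, 236 ± 18.4 and 162 ± 5.73 CPM. In the other direction, catalase (evm.model.Contig2.291) had 2.46 ± 1.02, 0.329 ± 0.349 and 8.78 ± 7.13 CPM, and an endo-1,3(4)-beta-glucanase hit (evm.model.Contig4.617) 17.4 ± 4.58, 7.39 ± 0.527 and 37.5 ± 14.2 CPM. Heat shock protein 60 (evm.model.Contig3.505), a mitochondrial chaperonin, had 301 ± 18.2, 384 ± 41.6 and 221 ± 37.0 CPM. At 48 h against 0 h, library size as the only scaling shifted the median log2 change of all genes by 0.36. The log2 changes there were -0.48 for the leucine gene, -0.28 for aspartate-semialdehyde dehydrogenase, -0.27 for the histidine gene and -0.45 for heat shock protein 60. That these genes were lower at 48 h than at 0 h may thus rest on the scaling.

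A hypothesis that arose from reading these examples was that amino acid biosynthesis genes fall from 12 h to 48 h. Among the 59 members left after all named and opposite-direction genes were taken out, 5 were higher and 15 lower, with a median log2 change of -0.13 (camera adjusted p = 0.0326, and 0.914 with an estimated correlation). That list was matched on process terms and also held genes of other roles, such as the hits to exosome component rrp43 and LEO1, so the hypothesis stays open. The median of all members was -0.15 and did not change sign under any scaling, whereas at 48 h against 0 h it was -0.11 and turned to 0.25 with library size only. A second hypothesis was that phosphate acquisition genes rise from 12 h to 48 h, after phosphate transporter evm.model.Contig5.400 (2.90) and evm.model.Contig13.180 (2.24). The remaining 21 members had a median of 0.13 (camera adjusted p = 0.869, and 0.914 with an estimated correlation), which leaves it undecided. Of them 6 were higher, among them another hit to phosphate permease pho-4 (evm.model.Contig2.114, 1.19), and 4 were lower. The phosphate list also held several genes of other roles, such as the hits to mitochondrial thiamine pyrophosphate carrier 1 and RNA polymerase II transcription factor B subunit 5. Its median therefore does not cover phosphate acquisition genes alone. A list for iron uptake matched mainly genes of other roles through annotation text, such as the GTP-binding proteins ypt1 and rhb1, so its test was set aside as uninformative, and whether iron uptake genes fall as a group was not tested. Trehalose, glycerol and osmotic stress genes gave 5 higher and 6 lower of 13 members at 12 h. They gave 4 and 6 at 48 h against 0 h, and 1 and 0 from 12 h to 48 h. Their medians were 0.12, -0.12 and 0.08 (camera adjusted p = 0.608, 0.608 and 0.663). The first had a camera direction of down, and the second turned to 0.24 with library size only. At 12 h, hits to trehalose-phosphate synthase (-1.12 and -1.26), trehalose-phosphatase (-0.98) and neutral trehalase (-1.24) lay below 0. Trehalose phosphorylase had 0.29, and some members had other roles, such as a mannosyl-oligosaccharide glucosidase hit.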
